A study of Mus musculus with 18 samples.

How the data were processed

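The data are gene-level values of poly(A) RNA from bone marrow macrophages of the mouse, in 18 libraries of 4 groups: Con (n = 3), LPS, STSABs and UVABs (n = 5 each). Replicates 4 and 5 of UVABs carry a shorter spelling in the labels, which the design text gives as the same treatment. Per the labels' protocols, RNA was extracted with Trizol, mRNA was selected with oligo(dT) beads, and libraries were made with dUTP in the second strand and sequenced from both ends on an Illumina NovaSeq. Per the submitters' processing notes, HISAT2 and the genome build mm39 were used. The counting tool, its strand setting, the annotation and versions are not given in the sources used here.

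The authors deposited a table of estimated counts for 16909 gene symbols, without normalization. Of its values 6.35% were not whole numbers, in 2017 genes, so they were treated as estimated counts and rounded to whole numbers before testing. Genes that could share reads with close relatives, such as members of interferon-induced families, are uncertain, and without the strand setting overlapping and antisense genes cannot be told apart. Because the table names genes only by symbol, and a reference of the build used was not at hand, no coordinates are given. Totals of 17588400 to 18675300 per library set the precision. Floors and the Poisson intervals of ratios against groups with few counts cover counting error only.

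Genes were filtered with filterByExpr by group, which left 12465 genes with 99.97% of the counts. Counts were scaled by TMM, and edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3) was fitted to all 18 libraries with group means only, so that all groups shared an estimate of the spread. The 6 contrasts were tested with Benjamini-Hochberg adjustment at 0.05. Comparisons of LPS with Con, of each AB group with LPS, and of UVABs with STSABs were the main ones, and those of the AB groups with Con secondary. Mean TMM factors were 1.51 in Con, 0.902 in LPS, 0.932 in STSABs and 0.928 in UVABs. A fold against a group without counts was taken against a floor of 3 counts over the group, and with 1 to 3 counts as a ratio with its exact Poisson interval of 95%. List medians were the same with such genes set at their bound.

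Before the data were examined, the groups, tests, alternatives, gene lists and the rule for named genes were fixed. The rule names a panel of 16 genes in each comparison, the 10 largest changes in each direction (5 for the comparisons of ABs with Con) among called genes with at least 5 CPM in the higher group and no overlap between the groups, and up to 4 members of a list with the smallest adjusted p. Symbols of predicted genes were left out, and some genes that the rule names are not reported here. The lists covered inflammatory cytokines and mediators, chemokines, interferon-stimulated genes, feedback inhibitors of NF-kB and cytokine signalling, M2 markers, Toll-like receptor signalling, MHC class II and co-stimulation, inflammasome and pyroptosis, efferocytosis, LXR targets, cholesterol synthesis, PPAR targets and fatty acid oxidation, fatty acid amide and endocannabinoid metabolism, glycolysis and HIF-1 targets, oxidative phosphorylation, the tricarboxylic acid cycle, NRF2 targets, the unfolded protein and integrated stress response, the cell cycle, p53 targets, lysosome and autophagy, and markers of macrophages, neutrophils, dendritic cells, T and NK cells, B cells, stromal cells, erythroid cells, mast cells and basophils, endothelial cells and platelets, and osteoclasts.

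Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over 124 tests of all lists and the 4 main comparisons, and again with an estimated correlation. Scores per library were compared with exact two-sided permutation tests, for which 3 against 5 libraries allow no p below 0.0179 and 5 against 5 none below 0.00794. Changes relative to Con used LPS libraries split into sets of 2 and 3, so that no library stood on both sides.

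The test was tested on simulated counts with the real means and library sizes, 250 changed genes per fold size over 5 runs. Changed genes were drawn only from those above a minimum expected count, and libraries were drawn independently. For UVABs against STSABs (12394 genes) it recovered 49.6% of genes changed 1.25-fold, 80.8% at 1.5-fold, 94% at 2-fold and 98% at 4-fold. For LPS against Con (12388 genes) it recovered 40.4%, 79.2%, 96.4% and 99.2%. Between 4.09% and 6.85% of the calls in the 6 simulated comparisons were false.

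Alternatives were DESeq2 size factors, upper-quartile scaling, DESeq2 1.42.0 and limma-voom as tests, no filter and a stricter filter, fits of only the groups compared, replicates 1 to 3 only, a term for replicates 1 to 3 against 4 and 5, the replicate number as a block, and each library left out in turn. Library totals without scaling factors, fits without replicate 2 of both AB groups, block fits of the AB groups alone, and list tests with an estimated correlation in 3 of these other fits were added after seeing the data. Whether the replicate numbers in the labels pair the libraries was checked by correlating, across genes, the deviations of same-numbered libraries from their group means. The numbers were taken to pair STSABs with UVABs, since all 5 correlations, from 0.116 to 0.540, exceeded 0.1. Yet STSABs replicate 5 correlated more with a UVABs library of another number (0.154) than with UVABs replicate 5 (0.137). Without the pair numbered 2, the correlations for numbers 3 and 5 were under 0.1 (0.0890 and 0.0508). The numbers paired no other groups.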

Results

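Poly(A) RNA of mouse bone marrow macrophages was sequenced in 18 libraries. The mock group (Con) had n = 3 libraries, and the LPS, STSABs and UVABs groups had n = 5 each. LPS is lipopolysaccharide, a component of the outer membrane of Gram-negative bacteria that activates macrophages through Toll-like receptor 4, and it was the positive control for inflammation. The STSABs and UVABs groups received apoptotic bodies (ABs), the membrane-bound fragments that dying cells shed. The ABs came from cells that the labels call hucMSC, had been induced with STS or with UV, and were named as anti-inflammatory treatments. The series title points to linolamide in such bodies and to mesenchymal stem cell therapy of abortion models. Nothing states whether the AB groups also received LPS, at what dose or time each treatment was given, or whether replicates were separate cultures or animals. The p-values therefore measure only the spread between these libraries, which may be technical.

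Estimated counts summed to between 18252500 and 18346800 per library in Con, 18089100 and 18582800 in LPS, 17588400 and 18675300 in STSABs, and 17851500 and 18312800 in UVABs. The first principal component of log2 CPM (estimated counts brought to a common library size) held 76.4% of the variance and parted Con from the other groups. The second component, with 12.8%, parted LPS from both AB groups. Replicate 2 of STSABs and replicate 2 of UVABs had the lowest scores on the second component (-31.8 and -29.8) and on PC3 (-21.5 and -27.2). Ribosomal protein genes took 5.98% ± 0.301 of the counts in Con (SD, n = 3), 3.56% ± 0.149 in LPS, 4.48% ± 0.286 in STSABs and 4.47% ± 0.255 in UVABs (SD, n = 5 each). Below, levels are mean CPM ± SD over the libraries of a group, and changes are log2 fold changes ± SE from edgeR's quasi-likelihood fit. The SE is an approximation, the absolute log2 fold change divided by the square root of the test's F. A gene is said to rise or fall where its Benjamini-Hochberg adjusted p from that test passed the threshold.

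**Figure D1:**
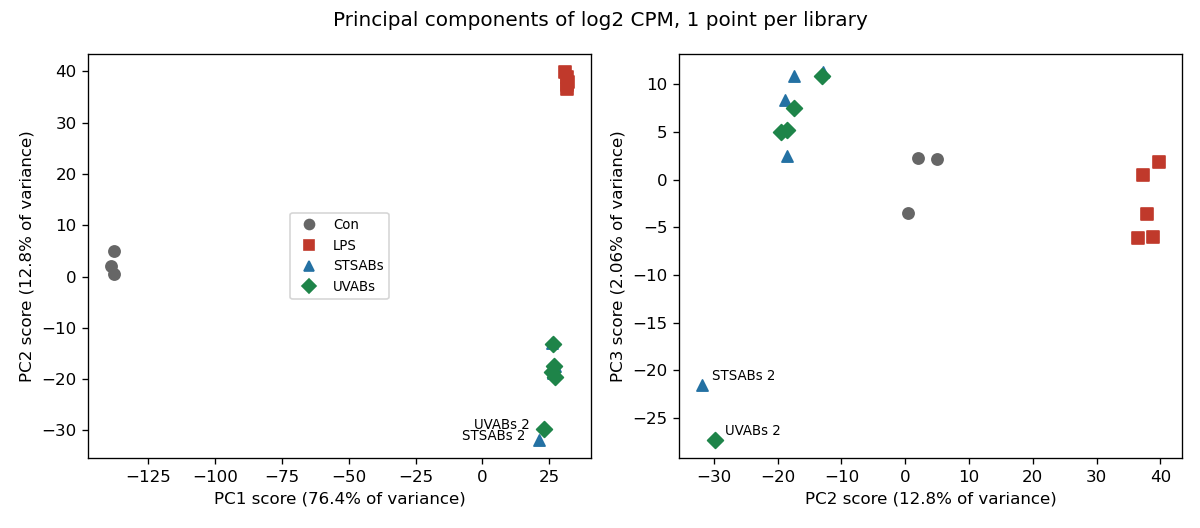
Principal component scores of log2 CPM, with 1 point per library, colour and shape by group; the axes carry the share of variance of each component. Con lies apart on PC1, LPS and the AB groups part on PC2, and replicate 2 of STSABs and of UVABs lie lowest on PC3, at -21.5 and -27.2.

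LPS against Con shows how the positive control for inflammation changed the macrophages. Il6, a pro-inflammatory cytokine, rose from 3.80 ± 0.502 CPM in Con to 1339 ± 44.5 in LPS (8.46 ± 0.10; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.16e-24). Tnf, another such cytokine, rose from 10.1 ± 0.703 to 613 ± 22.1 CPM (5.92 ± 0.16), and Il1b from 27.3 ± 3.34 to 4444 ± 209 CPM (7.35 ± 0.13). Nos2, the inducible nitric oxide synthase, rose from 0.843 ± 0.368 to 2677 ± 597 CPM (11.62 ± 0.26), and Cxcl10, an interferon-induced chemokine, from 1.90 ± 0.630 to 4601 ± 183 CPM (11.23 ± 0.17). Mrc1, the mannose receptor, fell from 284 ± 18.8 to 123 ± 4.50 CPM (-1.20 ± 0.07), and Tlr4, the receptor for LPS, from 158 ± 9.08 to 66.1 ± 1.82 CPM (-1.26 ± 0.08).

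The other inflammatory genes chosen beforehand also rose. Il12b, which encodes a subunit of interleukins 12 and 23, changed by 10.76 ± 0.36, Ptgs2, the inducible cyclooxygenase, by 10.55 ± 0.26, the chemokines Ccl2 and Ccl5 by 4.76 ± 0.15 and 5.67 ± 0.14, the interferon-induced Ifit1 by 9.24 ± 0.14, and the LPS co-receptor Cd14 by 2.28 ± 0.17. The anti-inflammatory cytokine Il10 had 0 counts in Con and 21.1 ± 2.67 CPM in LPS, at least 584-fold higher when Con is set at a floor of 3 counts over the group. Ifnb1, a type I interferon, had 1 count in Con and was 142 times higher in LPS (95% counting interval 25.1 to 5642). Arg1, an arginase often used as a marker of alternative activation, did not pass (36.3 ± 3.47 CPM in Con and 47.0 ± 8.90 in LPS, 0.37 ± 0.36, edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 0.339). Scaling by library totals alone turned the value to -0.38, not past the threshold. Arg1 passed at 0.38 in a fit of only LPS and Con, and at 0.37 without replicate 2 of both AB groups, whose spread enters the test.

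Among the largest increases were Nts, which encodes neurotensin (at least 626-fold), Il17rd (at least 355-fold), Apol9a (at least 318-fold), all with 0 counts in Con, and the integrin subunit Itgb8 (2658 times, interval 909 to 12891, 3 counts in Con). Ifi205, a member of an interferon-induced family, changed by 10.40 ± 0.17. The largest decreases were in Lpar5, a lysophosphatidic acid receptor (-6.92 ± 0.28), Pald1 (-6.32 ± 0.14), Vipr1, a receptor for vasoactive intestinal peptide (-6.20 ± 0.17), Amz1 (-6.09 ± 0.12), Akap5 (-6.08 ± 0.37), the potassium channel Kcnj10 (-6.00 ± 0.20), Cep131 (-5.98 ± 0.13), Aatk (-5.92 ± 0.14), Cand2 (-5.85 ± 0.24) and Il18r1, a subunit of the interleukin-18 receptor (-5.56 ± 0.19). For each called gene named in this comparison, all 5 LPS libraries lay on the same side of all 3 Con libraries. The naming rule required this of the largest changes, so for them it is not a separate result. Values of Apol9a, Ifi205, Ifit1, Ifit3, Trim30a, Clec10a, Cxcr2 and Ly6c2 are uncertain, since their estimated counts were not whole in most libraries, which can arise where reads are shared with close relatives; the cause was not tested.

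All 25 tested inflammatory cytokines and mediators rose in LPS (median log2 fold change 6.51; camera adjusted p = 1.85e-11). They included Acod1, the enzyme that makes itaconate (7.09 ± 0.09), and the cytokine subunit Il27 (8.45 ± 0.14). Of 19 chemokines, 18 rose and 1 fell (camera adjusted p = 7.10e-08), the latter being Ccl6 (-0.34 ± 0.08, named after its value was seen), with Ccl22 at 5.46 ± 0.10, Ccl4 at 5.41 ± 0.10 and Ccl3 at 5.04 ± 0.10. All 32 interferon-stimulated genes rose (camera adjusted p = 1.14e-18; adjusted p = 0.184 with an estimated correlation), among them Ifit3 (8.22 ± 0.12), Usp18 (6.28 ± 0.09) and Oasl1 (9.32 ± 0.13). Of 24 feedback inhibitors of NF-kB and cytokine signalling, 23 rose, 0 fell and 1 did not pass (camera adjusted p = 2.69e-10). Nfkbia, the inhibitor of NF-kB, changed by 2.82 ± 0.06, Nfkbiz by 5.07 ± 0.09, Il1rn, the interleukin-1 receptor antagonist, by 4.71 ± 0.09, and Trim30a by 4.06 ± 0.09. The calls for cytokines, chemokines and feedback inhibitors were the 3 that held with an estimated correlation, of 26 list calls over the 4 main comparisons.

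Of 30 Toll-like receptor signalling components, 23 rose, 4 fell and 3 did not pass (camera adjusted p = 0.000213; adjusted p = 0.120 with an estimated correlation). Risers included the NF-kB subunits Nfkb1 (2.72 ± 0.05) and Nfkb2 (3.10 ± 0.06) and the adaptor Myd88 (2.07 ± 0.06). Of 26 NRF2 targets and oxidative stress genes, 19 rose, 6 fell and 1 did not pass (camera adjusted p = 0.0144; adjusted p = 0.764 with an estimated correlation), with Txn1, thioredoxin, at 2.17 ± 0.06 and Slc7a11, the cystine transporter, at 2.37 ± 0.09. Of 35 cell cycle genes, 2 rose, 32 fell and 1 did not pass (camera adjusted p = 7.85e-07; adjusted p = 0.545 with an estimated correlation), with the cyclin Ccna2 at -2.04 ± 0.07, the replication helicase subunit Mcm7 at -1.84 ± 0.07 and Cdc20, an activator of the anaphase-promoting complex, at -1.96 ± 0.08.

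Markers of other cell types were measured alongside. Of 13 dendritic cell markers, 10 rose, 2 fell and 1 did not pass (camera adjusted p = 0.0374; adjusted p = 0.389 with an estimated correlation), with the chemokine receptor Ccr7 at 4.13 ± 0.09 and Fscn1 at 4.33 ± 0.12. Among 21 macrophage markers, 8 rose, 7 fell and 6 did not pass, with the Fc receptor Fcgr1 at 1.54 ± 0.05 and the signalling subunit Fcer1g at 1.21 ± 0.05. Of 16 neutrophil and granulocyte precursor markers, 8 rose, 4 fell and 4 did not pass, with Lcn2 at 2.71 ± 0.13 and Cxcr2 at -2.49 ± 0.19. In the smaller marker lists, the members that rose and those that fell numbered 4 and 3 of 9 for T and NK cells, 1 and 3 of 7 for B cells and plasma cells, 5 and 2 of 14 for stromal and mesenchymal cells, and 2 and 0 of 3 for erythroid cells. They numbered 2 and 3 of 8 for mast cells and basophils, 3 and 0 of 7 for endothelial cells and platelets, and 3 and 6 of 9 for osteoclasts.

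The remaining lists held members that moved both ways. Of 28 alternative activation (M2) markers 11 rose and 13 fell, with the lectin Clec10a at -3.02 ± 0.06 and the chemokine Ccl17 at 2.59 ± 0.08. Members that rose and fell numbered 10 and 6 of 17 for MHC class II antigen presentation and co-stimulation, 10 and 4 of 16 for inflammasome and pyroptosis, 11 and 13 of 29 for apoptotic cell uptake (efferocytosis), 8 and 6 of 17 for LXR targets and cholesterol efflux, and 10 and 9 of 23 for cholesterol synthesis. In further metabolic lists they numbered 8 and 16 of 26 for PPAR targets and fatty acid oxidation, 5 and 11 of 17 for fatty acid amide and endocannabinoid genes, 13 and 6 of 24 for glycolysis and HIF-1 targets, 20 and 7 of 36 for oxidative phosphorylation, and 6 and 12 of 22 for the tricarboxylic acid cycle. In stress and turnover lists they numbered 11 and 11 of 24 for the unfolded protein and integrated stress response, 13 and 11 of 26 for p53 targets and apoptosis regulators, and 15 and 14 of 31 for lysosome and autophagy. The 23 lists without a call had camera adjusted p-values from 0.129 to 0.934. Adjusted over the list alone, each count was the same except for 10 and 3 among dendritic cell markers and 19 and 7 in oxidative phosphorylation. Median, mean and test differed in sign for M2 markers, efferocytosis, LXR targets, fatty acid amide genes, lysosome and autophagy, and the macrophage, B cell, mast cell and osteoclast markers.

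In all, 4991 of 12465 tested genes were higher in LPS and 5361 lower, of which 2325 and 2615 changed by at least 2-fold (edgeR quasi-likelihood, Benjamini-Hochberg). Upper-quartile scaling gave 3754 higher and 6665 lower, so that 36.0% in place of 48.2% of the calls were higher, and moved the median of all genes from -0.03 to -0.31. Library totals alone gave 2365 higher and 8802 lower, 21.2% of the calls higher, with a median of -0.78. Under upper-quartile scaling, members that rose and fell went from 20 and 7 to 6 and 16 in oxidative phosphorylation, and to 8 and 16 in lysosome and autophagy, 7 and 12 in macrophage markers, 7 and 9 in LXR targets, 10 and 12 in cholesterol synthesis, and 13 and 13 in p53 targets; library totals alone also turned the balance in glycolysis (8 and 16), MHC class II (5 and 8), stress response (5 and 12), neutrophil (3 and 8) and endothelial (1 and 2) lists.

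Both AB groups were set against LPS to see how each anti-inflammatory treatment compared with the inflamed control. The chemokine Ccl2, which attracts monocytes, fell from 821 ± 53.5 CPM in LPS to 297 ± 28.5 in STSABs (-1.46 ± 0.10; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.25e-10) and 317 ± 66.3 in UVABs (-1.37 ± 0.10; adjusted p = 3.09e-10). Il6 fell from 1339 ± 44.5 CPM to 868 ± 50.4 and 909 ± 41.4 (-0.63 ± 0.05 and -0.56 ± 0.05), and Tnf from 613 ± 22.1 CPM to 386 ± 53.1 and 388 ± 62.8 (-0.67 ± 0.10 and -0.66 ± 0.10). The interferon-induced Ifit1 fell by 0.77 ± 0.07 in each comparison, and Il10 fell too (-1.09 ± 0.13 and -1.11 ± 0.13). Bnip3, a hypoxia-induced mitophagy receptor, rose from 24.9 ± 5.49 CPM in LPS to 136 ± 7.48 in STSABs and 135 ± 5.197 in UVABs (2.45 ± 0.10 and 2.44 ± 0.10). Values are for n = 5 libraries per group.

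Arg1 rose by 1.38 ± 0.30 in STSABs and 1.58 ± 0.30 in UVABs (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.000554 and 0.000143). Without the libraries numbered 2, where Arg1 was highest, the changes were 1.04 and 1.07, both still called. Cd14 rose (0.61 ± 0.13 and 0.69 ± 0.13), as did Mrc1 (0.32 ± 0.06 and 0.36 ± 0.06). Tlr4 fell (-0.75 ± 0.08 and -0.67 ± 0.08), and so did Cxcl10 (-0.39 ± 0.08 and -0.37 ± 0.08), Ptgs2 (-0.39 ± 0.11 and -0.36 ± 0.11) and Il1b (-0.23 ± 0.07 and -0.19 ± 0.07). Leaving out LPS replicate 1, 2, 3 or 4, or UVABs replicate 1, 3 or 5, ended the call of Il1b in UVABs (-0.16 to -0.19), as did library totals alone (-0.15). With replicates 1 to 3 only, the calls of Il1b were lost in both groups (-0.27 and -0.21). Ccl5 was 0.21 ± 0.09 in STSABs, not past the threshold, and rose by 0.25 ± 0.09 in UVABs, a call lost without LPS replicate 1 (0.20) or UVABs replicate 2 (0.17); its difference between the AB groups did not pass (0.04 ± 0.09). In STSABs Ccl5 passed without Con replicate 3, UVABs replicate 2 or 4 (0.21 each), LPS replicate 5 (0.24) or STSABs replicate 4 (0.25). It passed there also with replicates 1 to 3 only (0.33), with library totals alone (0.25), in a fit of only STSABs and LPS (0.22), under DESeq2 size factors and in the DESeq2 test (0.21 each), and with the replicate number as a block or a term for replicates 1 to 3 against 4 and 5 (0.20 each). Values that did not pass were 0.15 ± 0.12 and 0.19 ± 0.12 for Nos2, -0.38 ± 0.19 and -0.37 ± 0.19 for Ifnb1, and -0.35 ± 0.17 and -0.38 ± 0.17 for Il12b. Without LPS replicate 5, Il12b (-0.43 and -0.46), Ifnb1 (-0.49 and -0.48) and, in UVABs, Nos2 (0.30) passed. Ifnb1 in UVABs also passed without UVABs replicate 1 (-0.50), and Il12b without UVABs replicate 2 (-0.35 in STSABs), STSABs replicate 2 (-0.38 in UVABs) or UVABs replicate 4 (-0.45 in UVABs), and in a fit of only UVABs and LPS (-0.37). Without both libraries numbered 2, Il12b passed at -0.20 and -0.23.

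**Figure D2:**
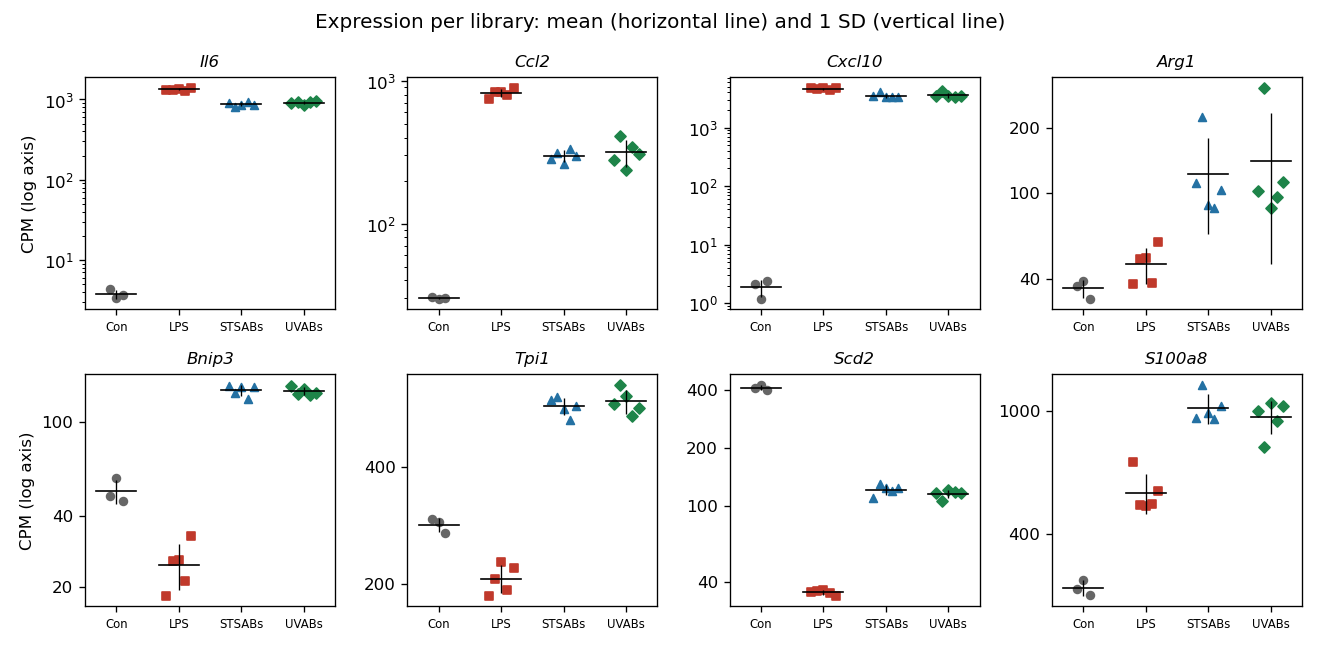
CPM on log axes for 8 genes in each library, by group (n = 3 for Con, 5 for the others), with the mean as a horizontal line and 1 SD as a vertical line. Il6, Ccl2 and Cxcl10 lie far above Con in LPS and lower in both AB groups than in LPS; Arg1 was highest in replicate 2 of both AB groups; Bnip3, Tpi1, Scd2 and S100a8 lie higher in both AB groups than in LPS.

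Genes with the largest increases were shared to a large part. Ddit4, an inhibitor of mTORC1 induced by stress and hypoxia, rose by 3.39 ± 0.47 in STSABs and 3.42 ± 0.47 in UVABs (2.94 and 2.90 without the libraries numbered 2). Klrb1b, a C-type lectin-like receptor gene, changed by 2.83 ± 0.18 and 2.82 ± 0.18, the muscle-type glycogen synthase Gys1 by 2.57 ± 0.07 and 2.55 ± 0.07, Pou6f1 by 2.46 ± 0.14 and 2.48 ± 0.14, and Trib3, induced in the integrated stress response, by 2.41 ± 0.19 and 2.35 ± 0.20. Egln3, a prolyl hydroxylase that is itself a HIF-1 target, changed by 2.37 ± 0.14 and 2.29 ± 0.14, the lipid droplet protein gene Hilpda by 2.35 ± 0.27 and 2.46 ± 0.27, and the glutaminase Gls2 by 2.34 ± 0.33 and 2.35 ± 0.33. Gdf11 was among the 10 in STSABs (2.71 ± 0.18) and rose by 2.55 ± 0.19 in UVABs, where it was under the minimum of 5 CPM. Grasp was among the 10 in UVABs (2.30 ± 0.18) and rose by 2.18 ± 0.18 in STSABs.

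The largest decreases were in Ccl24, a chemokine for eosinophils (-3.59 ± 0.27 in STSABs and -3.65 ± 0.27 in UVABs), Ereg, an epidermal growth factor receptor ligand (-2.92 ± 0.15 and -2.67 ± 0.15), Spic, a transcription factor of iron-recycling macrophages (-2.83 ± 0.16 and -2.82 ± 0.16), and Shisa3 (-2.59 ± 0.23 and -3.04 ± 0.25). Lad1 (-2.38 ± 0.17 and -2.39 ± 0.17), Pla2g4f (-2.32 ± 0.12 and -2.50 ± 0.12), Apol9a (-2.26 ± 0.10 and -2.32 ± 0.10), Atp13a4 (-2.21 ± 0.18 and -2.46 ± 0.19) and Clic5 (-2.14 ± 0.15 and -2.26 ± 0.15) fell as well. Col5a3 was among the 10 in STSABs (-2.12 ± 0.10; -2.22 ± 0.11 in UVABs) and Ccdc149 in UVABs (-2.27 ± 0.15; -2.04 ± 0.15 in STSABs). The naming rule required that the largest changes had no overlap between the groups. For called genes named with an SE, all 5 AB libraries of a group lay on the same side of the 5 LPS libraries. Exceptions were Il1b and Ptgs2 in both groups and Ccl5 in UVABs. Values of Apol9a, Ifit1, Gbp3, Scd2, Lyz2 and Mertk are uncertain for the same reason.

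**Figure D3:**
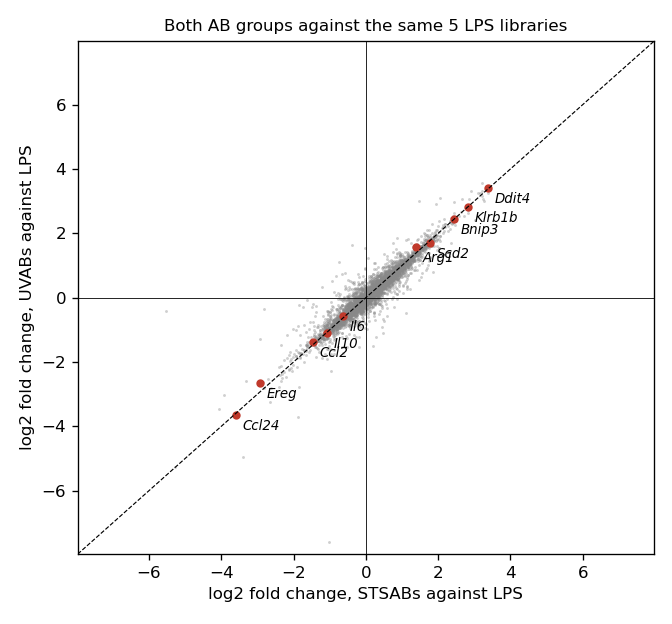
Log2 fold change against LPS of each of the 12465 tested genes, in STSABs on the x axis and UVABs on the y axis; the dashed line marks equal change, and red points are named genes. The points lie along the line, with a correlation across genes of 0.951.

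Chemokines were lower in both AB groups. Of 19 tested, 0 rose, 15 fell and 4 did not pass in STSABs (camera adjusted p = 0.000126; adjusted p = 0.120 with an estimated correlation). In UVABs 1 rose, 14 fell and 4 did not pass (camera adjusted p = 0.000227; adjusted p = 0.120 with an estimated correlation). Ccl3 changed by -1.06 ± 0.07 and -1.04 ± 0.07, and Ccl12 by -1.57 ± 0.11 and -1.46 ± 0.11. Of 32 interferon-stimulated genes, 2 rose, 24 fell and 6 did not pass in STSABs (camera adjusted p = 0.000126; adjusted p = 0.627 with an estimated correlation), and 2 rose, 22 fell and 8 did not pass in UVABs (camera adjusted p = 0.000128; adjusted p = 0.627 with an estimated correlation). The interferon-induced GTPases Ifi47 (-0.84 ± 0.06 and -0.83 ± 0.06), Irgm1 (-0.77 ± 0.05 and -0.74 ± 0.05) and Gbp3 (-0.69 ± 0.06 and -0.68 ± 0.06) were among those that fell. When the libraries numbered 2 were left out, 14 and 15 chemokines and 24 and 23 interferon-stimulated genes fell. Inflammatory cytokines and mediators as a list had no call (5 rose and 13 fell of 25 in STSABs, 5 rose and 11 fell in UVABs; camera adjusted p = 0.179 and 0.241). In STSABs, Csf1, the macrophage growth factor, changed by -1.06 ± 0.05, the alarmin Il33 by -1.78 ± 0.11 and the co-stimulatory ligand Tnfsf9 by 1.62 ± 0.08. Their changes in UVABs were -1.08, -1.75 and 1.65. M2 markers had no call either (4 rose and 12 fell of 28 in STSABs, 4 rose and 13 fell in UVABs; camera adjusted p = 0.241 in each). Their members with the smallest adjusted p in STSABs included the scavenger receptor Cd36 (-0.78 ± 0.07) and the angiogenic factor Vegfa (2.12 ± 0.18). Both are known also outside alternative activation, and they changed by -0.73 and 2.16 in UVABs.

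Glycolysis and HIF-1 targets rose together in both AB groups. Of 24 members, 22 rose and 0 fell in STSABs (median 0.62; camera adjusted p = 2.69e-10; adjusted p = 0.317 with an estimated correlation), and 22 rose in UVABs (median 0.60; camera adjusted p = 2.69e-10; adjusted p = 0.317 with an estimated correlation). Adjusted over the list alone, all 24 rose in each. Without the libraries numbered 2, in which the HIF-1 target Vegfa was highest, 23 and 22 rose. Tpi1, triosephosphate isomerase, went from 206 ± 17.1 CPM in LPS to 572 ± 29.6 in STSABs (1.47 ± 0.06) and 589 ± 42.0 in UVABs (1.52 ± 0.06). The glycolytic enzyme gene Pgam1 rose by 0.80 ± 0.05 in each, and Slc16a3, a lactate exporter, by 1.87 ± 0.11 and 1.94 ± 0.11.

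Markers of neutrophils and granulocyte precursors moved with that group. All 16 rose in STSABs (median 0.84; camera adjusted p = 4.79e-05; adjusted p = 0.400 with an estimated correlation). In UVABs 14 rose and 2 did not pass (median 0.67; camera adjusted p = 0.000227; adjusted p = 0.474 with an estimated correlation). S100a8, which encodes a subunit of calprotectin, changed by 0.91 ± 0.09 and 0.81 ± 0.09, the lactoferrin gene Ltf by 1.16 ± 0.13 and 1.01 ± 0.13, and the granulocyte transcription factor Cebpe by 0.96 ± 0.11 and 0.85 ± 0.11. Of 8 mast cell and basophil markers, 6 rose and 1 fell in STSABs (camera adjusted p = 0.0248; adjusted p = 0.545 with an estimated correlation) and 6 rose and 1 fell in UVABs (camera adjusted p = 0.0617). Neutrophil markers that rose without the libraries numbered 2 were 15 in each AB group. In STSABs the transcription factor Gata2 changed by 1.96 ± 0.14 and the basophil protease Prss34 by 1.51 ± 0.23 (1.83 and 1.17 in UVABs). Of 21 macrophage markers, 8 rose and 9 fell in STSABs and 8 rose and 7 fell in UVABs (camera adjusted p = 0.825 and 0.943). In STSABs, Spi1, the myeloid transcription factor PU.1, changed by -0.44 ± 0.05 and the lysozyme gene Lyz2 by -0.45 ± 0.06. Csf1r, the receptor for Csf1, changed there by -0.46 ± 0.07 and the efferocytosis receptor Mertk by -0.58 ± 0.09. The changes of these genes in UVABs were -0.44, -0.37, -0.42 and -0.59, in the same order.

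Sterol genes also rose in both AB groups. Of 23 cholesterol synthesis genes, 17 rose, 0 fell and 6 did not pass in STSABs (camera adjusted p = 0.000131; adjusted p = 0.591 with an estimated correlation), and 17 rose in UVABs (camera adjusted p = 0.000227; adjusted p = 0.600 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, changed by 0.88 ± 0.08 and 0.83 ± 0.08, the squalene synthase Fdft1 by 1.10 ± 0.12 and 1.04 ± 0.12, and Sc5d by 1.04 ± 0.11 and 0.97 ± 0.11. Of 17 LXR targets and cholesterol efflux genes, 11 rose and 1 fell in each AB group (camera adjusted p = 0.0201 and 0.0175; adjusted p = 0.297 in each with an estimated correlation). Members with the smallest adjusted p included genes of fatty acid desaturation and elongation. Scd2, a fatty acid desaturase, rose by 1.77 ± 0.05 and 1.70 ± 0.05, and Elovl5, a fatty acid elongase, by 0.76 ± 0.06 and 0.77 ± 0.06, while Npc1, a lysosomal cholesterol transporter, fell (-0.55 ± 0.05 and -0.53 ± 0.05).

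NRF2 targets and oxidative stress genes were lower. Of 26, 1 rose, 18 fell and 7 did not pass in STSABs (camera adjusted p = 0.000257; adjusted p = 0.597 with an estimated correlation) and 3 rose, 18 fell and 5 did not pass in UVABs (camera adjusted p = 0.000542; adjusted p = 0.614 with an estimated correlation). Srxn1, sulfiredoxin, changed by -1.10 ± 0.09 and -1.02 ± 0.09, Txnrd1, thioredoxin reductase, by -0.86 ± 0.07 and -0.87 ± 0.07, and Slc7a11 by -0.73 ± 0.07 and -0.70 ± 0.07. Fatty acid amide and endocannabinoid genes, chosen because of the linolamide in the series title, had no call as a list (7 rose and 6 fell of 17 in STSABs, 6 rose and 6 fell in UVABs). In STSABs, Faah, the enzyme that degrades fatty acid amides, rose by 1.41 ± 0.09, and Mgll, monoacylglycerol lipase, fell (-0.52 ± 0.10). Their changes in UVABs were alike, at 1.37 and -0.59. In the unfolded protein and integrated stress response 12 rose and 6 fell of 24 in each AB group. In STSABs, the asparagine synthetase gene Asns changed by 0.82 ± 0.10 and Phgdh, of serine synthesis, by 0.61 ± 0.07 (0.74 and 0.49 in UVABs).

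The other lists had no call in either comparison. Members that rose and fell numbered 4 and 0 in STSABs and 6 and 0 in UVABs of 7 endothelial and platelet markers, and 7 and 2 in each of 13 dendritic cell, 4 and 5 in each of 14 stromal and mesenchymal, 1 and 1 in each of 9 T and NK cell, 1 and 1 in each of 3 erythroid and 1 and 3 in each of 9 osteoclast markers. For B cells and plasma cells they numbered 0 and 1 in STSABs and 1 and 1 in UVABs of 7 markers. In signalling lists they numbered 9 and 7 in STSABs and 7 and 7 in UVABs of 24 feedback inhibitors, 5 and 11 in STSABs and 4 and 10 in UVABs of 30 Toll-like receptor signalling components, 5 and 7 in STSABs and 5 and 6 in UVABs of 16 inflammasome genes, and 9 and 2 in each of 17 MHC class II and co-stimulation genes. In metabolic lists they numbered 7 and 7 in STSABs and 6 and 5 in UVABs of 26 PPAR and fatty acid oxidation genes, 4 and 10 in STSABs and 5 and 9 in UVABs of 36 oxidative phosphorylation genes, and 3 and 8 in each of 22 tricarboxylic acid cycle genes. They numbered 9 and 8 in STSABs and 10 and 7 in UVABs of 29 efferocytosis genes, 6 and 10 in STSABs and 8 and 11 in UVABs of 31 lysosome and autophagy genes, 11 and 6 in STSABs and 12 and 5 in UVABs of 35 cell cycle genes, and 10 and 9 in each of 26 p53 targets. Lists without a call had camera adjusted p-values from 0.0875 to 0.860 in STSABs and from 0.0617 to 0.943 in UVABs.

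Adjusted over the list alone, members that rose and fell in STSABs numbered 1 and 15 for chemokines, 5 and 14 for cytokines, 6 and 7 for PPAR targets, 12 and 7 for the stress response and 5 and 0 for endothelial markers. Adjusted over the list alone, they numbered in UVABs 2 and 23 for interferon-stimulated genes, 5 and 12 for cytokines, 16 and 0 for neutrophil, 8 and 2 for dendritic cell, 0 and 1 for B cell, 4 and 6 for stromal and 7 and 0 for endothelial markers, and 4 and 7 for oxidative phosphorylation. Apart from glycolysis, all other counts were the same. Median, mean and test differed in sign in STSABs for B cell and erythroid markers, and in UVABs for the inflammasome, efferocytosis and lysosome lists and for macrophage and B cell markers.

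**Figure D4:**
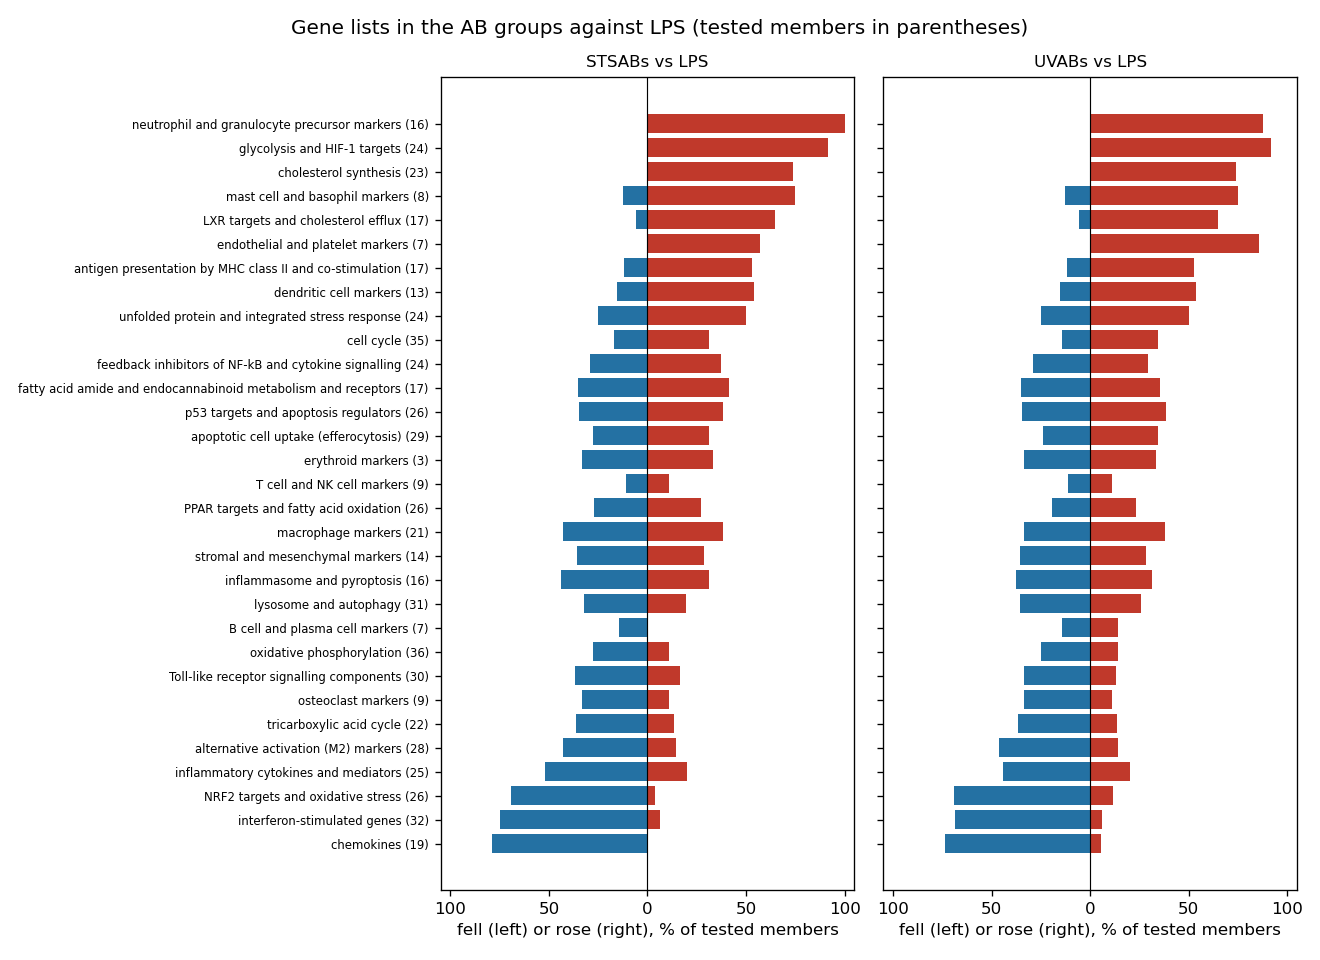
Share of the tested members of each gene list that rose (red, to the right) or fell (blue, to the left) against LPS, in percent, for STSABs and UVABs; the number of tested members stands in parentheses. Lists are ordered by the balance of rises and falls in STSABs. Neutrophil markers, glycolysis and HIF-1 targets and cholesterol synthesis lie at the top, and chemokines, interferon-stimulated genes and NRF2 targets at the bottom. In UVABs a larger share of endothelial and platelet markers than of cholesterol synthesis genes rose.

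Against LPS, 3544 genes were higher and 3614 lower in STSABs (603 and 311 by at least 2-fold), and 3566 were higher and 3595 lower in UVABs (586 and 284; edgeR quasi-likelihood, Benjamini-Hochberg). Without the libraries numbered 2 the counts were 3588 and 3703 in STSABs and 3602 and 3730 in UVABs. Library totals alone evened out or turned small surpluses in oxidative phosphorylation (6 and 6 in STSABs, 7 and 6 in UVABs), the tricarboxylic acid cycle in STSABs (6 and 6), the inflammasome (6 and 5, 5 and 3), lysosome genes in UVABs (9 and 9), macrophage markers in STSABs (9 and 8), PPAR targets in STSABs (7 and 5), feedback inhibitors in UVABs (10 and 5), fatty acid amide genes in UVABs (6 and 5) and stromal markers (4 and 4 in each). Without the libraries numbered 2, PPAR targets had 5 and 6 in each, macrophage markers 9 and 9 in UVABs, feedback inhibitors 9 and 7 in UVABs, and the endothelial and platelet list passed (camera adjusted p = 0.0364 and 0.0323; adjusted p = 0.393 in each with an estimated correlation in that fit, 0.504 and 0.474 with all libraries). Mast cell and basophil markers in UVABs also passed then (camera adjusted p = 0.0364; adjusted p = 0.665 with an estimated correlation in that fit, 0.600 with all libraries), and with replicates 1 to 3 only (camera adjusted p = 0.0396; adjusted p = 0.4934 with an estimated correlation).

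Both comparisons called 6572 genes in the same direction, 3260 higher and 3312 lower, and 0 in opposite directions. Independent lists of these sizes would share 1014 and 1042. Because the same LPS libraries enter both, counts for all groups were simulated with both AB groups at the LPS means. They shared 0 calls, which says little, since each simulated comparison called a median of 0 genes. Their correlation across genes was 0.504 against the observed 0.951, and their covariance 0.0164 against 0.306. Simulated libraries were independent, so these values leave out the deviations that same-numbered STSABs and UVABs libraries share. Those deviations also stay in the splits of the LPS libraries that follow. With the LPS libraries split between the comparisons, the median over 20 splits was 5010.5 shared calls (4931 to 5083), with a correlation of 0.803 and a covariance of 0.297. Genes are not independent replicates, so these correlations are descriptions.

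The direction of these changes relative to Con was described on genes that part of the LPS libraries called against Con at 2-fold or more, with the rest used as reference. Of a median of 4986 such genes, 66.0% moved toward Con in STSABs (64.9 to 66.5 over 20 splits of the LPS libraries), and the median gene moved 9.35% of the way. In UVABs 65.7% moved toward Con (64.3 to 66.8), by 8.99% of the way at the median. The share was 61.8% and 61.1% for genes raised by LPS and 69.6% and 69.7% for genes lowered by it, in STSABs and UVABs.

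UVABs against STSABs asks whether the way the bodies were induced made a difference to the macrophages. Of 12465 genes tested, 0 were higher and 0 lower (edgeR quasi-likelihood, Benjamini-Hochberg). Of these genes 198 had an unadjusted p under 0.05, where 623 would be due if the p-values were uniform. That fit leaves out the pairing by replicate number, and an edgeR fit of the AB groups alone with it as a block gave 457. The shortfall thus depends on the fit and does not show that the groups are more alike than chance. DESeq2 called 0, with 169 under 0.05, and limma-voom 0, with 191. Arg1 was at 122 ± 57.6 CPM in STSABs and 140.2 ± 93.0 in UVABs, Ccl2 at 297 ± 28.5 and 317 ± 66.3, and Il6 at 868 ± 50.4 and 909 ± 41.4 (SD, n = 5 each), with log2 differences of 0.20 ± 0.29, 0.09 ± 0.10 and 0.07 ± 0.05. Without UVABs replicate 2 the differences of Arg1 and Ccl2 turned to -0.30 and -0.02. The 95% interval of the fold change lay within 1.5-fold for 86.3% of the genes and within 2-fold for 95.1%, and reached 2-fold for 617 genes, for which such a difference stays open. In every list 0 members passed, also adjusted over the list alone.

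Small shifts spread over the markers of 3 cell types. The neutrophil list had a median of -0.12 (camera adjusted p = 0.000257; adjusted p = 0.475 with an estimated correlation), macrophage markers 0.05 (camera adjusted p = 0.0220; adjusted p = 0.400 with an estimated correlation), and mast cell and basophil markers -0.13 (camera adjusted p = 0.0243; adjusted p = 0.545 with an estimated correlation). Without the libraries numbered 2, their camera adjusted p-values were 0.316, 0.316 and 0.456, and with replicates 1 to 3 only the macrophage and mast cell calls were lost (0.0592 and 0.0512) and the cell cycle list gained a call (camera adjusted p = 0.0396; adjusted p = 0.841 with an estimated correlation). The other 28 lists had camera adjusted p-values from 0.129 to 0.992. Median, mean and test differed in sign for feedback inhibitors, LXR targets, PPAR targets, glycolysis and erythroid markers.

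Against Con, both AB groups had higher levels of inflammatory transcripts. Tnf was higher by 5.25 ± 0.15 in STSABs and 5.26 ± 0.15 in UVABs, Il1b by 7.11 ± 0.12 and 7.15 ± 0.12, Il6 by 7.83 ± 0.09 and 7.90 ± 0.10, and Nos2 by 11.77 ± 0.26 and 11.81 ± 0.26. Cxcl10 was higher by 10.84 ± 0.17 and 10.86 ± 0.17, Plat, tissue plasminogen activator, by 10.80 ± 0.20 and 10.78 ± 0.20, and Cd14 by 2.88 ± 0.17 and 2.96 ± 0.17. Arg1 was higher too (1.75 ± 0.36 and 1.95 ± 0.37). Mrc1 was lower (-0.89 ± 0.07 and -0.85 ± 0.07), as was Tlr4 (-2.01 ± 0.09 and -1.93 ± 0.09). Il10, without counts in Con, was at least 275-fold and 270.3-fold higher, and Nts at least 445-fold and 428-fold. Coch, with 1 count in Con, was 4466 times higher in STSABs (95% counting interval 801 to 176425) and 4357 times in UVABs (782 to 172122). The largest decreases were in Lpar5 (-6.29 ± 0.26 and -6.00 ± 0.25), Pald1 (-6.17 ± 0.14 and -6.22 ± 0.14) and Vipr1 (-5.79 ± 0.16 and -5.79 ± 0.16).

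All 25 inflammatory cytokines and mediators and all 32 interferon-stimulated genes were higher than in Con in both AB groups. Since it is not stated whether these groups also received LPS, the rise cannot be credited to the apoptotic bodies alone. Of 24 glycolysis and HIF-1 targets, 23 rose and 0 fell in each AB group (medians 1.27 and 1.32), and 13 of 16 neutrophil markers rose and 2 fell in each. Of 35 cell cycle genes 1 rose and 32 fell in each. Adjusted over the list alone, these counts were the same. In STSABs 4989 genes were higher and 5313 lower than in Con, and in UVABs 5013 and 5288 (edgeR quasi-likelihood, Benjamini-Hochberg). Upper-quartile scaling gave 3822 and 6646 in STSABs and 3836 and 6622 in UVABs, so that 36.5% in place of 48.4% and 36.7% in place of 48.7% of the calls were higher, with a median of -0.31 for all genes in each. Library totals alone gave 2510 and 8511 in STSABs and 2504 and 8523 in UVABs, so that 22.8% and 22.7% were higher, with a median of -0.74 in each.

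Scores of 4 lists per library, the mean of log2(CPM + 1) over the members, were compared with an exact two-sided permutation test, adjusted by Benjamini-Hochberg over 24 comparisons. LPS exceeded Con by 4.90 for cytokines, 5.93 for interferon-stimulated genes and 4.11 for chemokines, each with exact p = 0.0179, the smallest that 56 assignments allow, and by 0.08 for M2 markers (exact p = 0.0357, adjusted p = 0.0429), which became 0.14 with a pseudocount of 0.1 (exact p = 0.0179, adjusted p = 0.0226). Against LPS, the scores of STSABs changed by -0.18 for cytokines, -0.33 for interferon-stimulated genes, -0.74 for chemokines and -0.15 for M2 markers, and those of UVABs by -0.15, -0.32, -0.70 and -0.14. All these had exact p = 0.00794, the smallest that 252 assignments allow (adjusted p = 0.0226), so that all 5 AB libraries lay below all 5 LPS libraries. Such a test asks whether a score differs, not whether its list changed more than other genes. Of all tested genes, 57.4% were called against LPS in each AB group. Camera called neither the cytokine nor the M2 list there. The M2 and chemokine lists share Ccl17, Ccl22 and Ccl24, and Ccl24 fell strongly, so the falls of these scores are not separate results. UVABs and STSABs differed by 0.03 for cytokines (exact p = 0.310), 0.01 for interferon-stimulated genes (exact p = 0.865), 0.05 for chemokines (exact p = 0.492) and 0.00 for M2 markers (exact p = 0.825). Of the 24 comparisons 20 passed.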

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

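The splits of the samples, the marker lists of other cell types and the simulated recovery were set before their results were seen, whereas the tests of library size, of a batch, of the direction of change, of the replicate block, of scaling, of human RNA, of granulocytes and of the libraries numbered 2 were chosen only after the result was seen.

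In 456 groups of 5 values, 58 held a library far from the other 4 by Dixon's test, where chance alone gives about 1 in 20. UVABs replicate 2 accounted for 25 of them and STSABs replicate 2 for 19. Both were far from their groups in Arg1, at 223 (others 85.2 to 111) CPM in STSABs and 306 (others 85.0 to 112) in UVABs, and in Ddit4, at 41.2 (others 10.99 to 18.02) and 44.4 (others 11.6 to 17.6). High values came in pairs also for Cd14, at 1425 (others 957 to 1079) and 1765 (others 956 to 1050.2) CPM, Klrb1b, at 60.7 (others 38.1 to 42.9) and 69.5 (others 36.4 to 41.2), Hilpda, at 87.5 (others 39.1 to 44.0) and 98.6 (others 40.9 to 50.6), Gls2, at 40.2 (others 14.9 to 18.02) and 41.5 (others 13.5 to 19.1), Vegfa, at 595 (others 321 to 351) and 619 (others 326 to 362), and Grasp, at 27.7 (others 15.8 to 18.6) and 29.5 (others 16.2 to 19.1). Low values came in pairs for Il12b, at 1621 (others 3190.5 to 3399) and 1619 (others 3075 to 3429) CPM, Tnf, at 292 (others 399 to 419.5) and 277 (others 405 to 430.4), Lad1, at 22.1 (others 38.1 to 43.0) and 19.9 (others 38.3 to 44.96), and Shisa3, at 0.182 (others 0.869 to 1.12) and 0.240 (others 0.646 to 0.788).

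By the same test, STSABs replicate 2 alone was far from its group in Sesn2 at 43.6 (others 28.1 to 30.0) CPM, Gata2 at 88.6 (others 47.8 to 57.8), Hdc at 810.5 (others 576 to 634), Abhd4 at 31.97 (others 25.9 to 27.4) and Ifit3 at 887 (others 1040.5 to 1076). Its score was 9.47 (others 9.58 to 9.62) for interferon-stimulated genes and 2.10 (others 1.73 to 1.81) for B cell and plasma cell markers, for which UVABs replicate 2 was also highest, at 2.11 (others 1.75 to 1.92), without passing that test. UVABs replicate 2 alone was far from its group in Nts at 9.46 (others 16.1 to 17.5) CPM, Cxcl10 at 4258 (others 3313 to 3429.6), Il17rd at 2.81 (others 5.46 to 6.52), Akap5 at 1.56 (others 0.175 to 0.424), Ccl3 at 624 (others 712 to 729.6), Csf3r at 53.6 (others 71.3 to 77.2) and Tcf4 at 169 (others 230.0 to 245). The same held for Gdf11 at 5.87 (others 3.94 to 4.34) CPM, Hmgcs1 at 104 (others 122 to 130.0), Csf1r at 229.5 (others 172 to 188) and Mertk at 274 (others 380.3 to 403), and for its scores of erythroid markers at 3.18 (others 3.35 to 3.41) and osteoclast markers at 4.56 (others 4.26 to 4.29).

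The remaining 14 values were spread over 6 libraries. LPS replicate 5 stood apart in Il12b at 2890.3 (others 3770.0 to 4115) CPM, Il1b at 4083 (others 4478 to 4622) and Gbp3 at 834 (others 784 to 797). LPS replicate 1 did so in Ltf at 129 (others 93.1 to 102) CPM, Ccdc149 at 12.0 (others 7.92 to 9.07) and the share of ribosomal protein genes at 3.82 (others 3.44 to 3.54) percent. LPS replicate 3 stood apart in Amz1 at 1.47 (others 0.675 to 0.838) CPM. STSABs replicate 4 did so in Il18r1 at 2.16 (others 3.30 to 3.76) CPM, Nfkbia at 949 (others 1044 to 1057), Tnfsf9 at 67.4 (others 84.6 to 91.3) and Sc5d at 16.3 (others 20.2 to 21.2), and STSABs replicate 1 in Pgam1 at 813 (others 765 to 774). UVABs replicate 4 stood apart in Fcer1g at 689.5 (others 723 to 728) CPM and Egln3 at 66.0 (others 83.9 to 90.2).

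The shared position of the libraries numbered 2 is not accounted for by library size, since 1 of these 2 totals lay outside its group's range (17588400 in STSABs), or by a batch of all libraries numbered 2, since deviations of LPS replicate 2 correlated across genes with theirs at 0.0253 and 0.00804. A larger step in the direction from LPS to the AB groups cannot be told apart: correlations across genes with that direction were low, 0.175 in UVABs and 0.262 in STSABs, but on the second component, which parted LPS from the AB groups, these libraries lay farthest from LPS (-29.8 and -31.8, the other AB libraries at -19.5 to -12.9). RNA from cells of another type cannot be told apart: 2 of 9 marker lists, B cells and endothelium with platelets, were above the next library by more than the range of the other 4 in both, which that explanation needs. Yet of their members above 5 CPM only the platelet gene Ppbp was so in both (75.6 and 102 CPM), and reading single members was decided after the lists were seen. A difference between AB preparations or cultures that share a number was not tested and may also apply.

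The rise of glycolysis and HIF-1 targets against LPS is not explained by scaling, since at least 22 members rose under each of 3 other scalings, nor by the libraries numbered 2, without which 23 rose in STSABs and 22 in UVABs. A larger share of granulocytes cannot be told apart, since granulocytes express these genes too and of 21 members that rose in both groups only 2, Bnip3 and Egln3, lay above every neutrophil, mast cell and basophil marker by more than 2 standard errors (at most 1.96 ± 0.14 in STSABs and 1.83 ± 0.14 in UVABs, both for Gata2). Human RNA from the bodies counted on mouse genes cannot be told apart either: the stromal list had medians of -0.14 and -0.16, both 0.76 below the glycolysis list, but its members spread by 1.03 and 0.983 (interquartile ranges). An effect of the treatments named in the design may also apply, and stays open as untested.

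The lack of called genes between UVABs and STSABs is unlikely to come from too few libraries for 2-fold differences, except among genes with few counts. Simulated data of this size recovered 94% of such differences in genes with at least 10 expected counts. In the real data the 95% interval lay within 2-fold for 95.1% of the genes. The simulation held no paired or outlying libraries, so its recovery may be too high. Of its unchanged genes 4.92% had an unadjusted p under 0.05, against 198 of 12465 real genes. A fit of the AB groups with the replicate number as a block also called 0 genes (edgeR quasi-likelihood, 457 at an unadjusted p under 0.05). The other splits say nothing of chance here, since with 0 genes called in the real one all 100 splits, drawn at random from the 126 possible ones of the 10 libraries, reach its count; the highest other called 1140. That split put replicates 1 and 2 of both groups on the same side and parted only 1 numbered pair, and the 7 drawn splits that called genes point to a structure of the samples. Among the drawn splits, 12 others part all 5 numbered pairs, and the highest of them called 0.

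For the other comparisons only 1 of the splits run, the real one, reached its count. Chance in how these libraries fell into groups is thus an unlikely source, though the share cannot go below 1 of the splits run. Chance between cultures or animals cannot be judged, since what the replicates are is not stated. The real and highest other counts were 10352 and 3272 for LPS against Con (56 splits), 7158 and 2282 for STSABs against LPS (100 drawn of 126 splits), 7161 and 2075 for UVABs against LPS (100 drawn of 126), 10302 and 4640 for STSABs against Con (56 splits), and 10301 and 4383 for UVABs against Con (56 splits).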

How the results depend on the processing

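Library totals without scaling factors, fits without the libraries numbered 2, block fits of the AB groups alone and estimated correlations within other fits were chosen only after seeing the data. Of 272 gene results, 8105 of 8192 values under alternatives kept direction and side of the threshold, 12 lost the call and 28 gained it, in 10 results, of Arg1, Il1b, Il12b, Ccl5, Ifnb1 and Nos2. Another 47 changed sign without a call on either side, 46 between UVABs and STSABs and 1 of Arg1 in LPS against Con (library totals only, -0.38). Of the called values, 0 changed sign. Many of these genes were named for large changes or small adjusted p in the main fit. Many alternatives left out only 1 library. Agreement was thus likely and does not extend to genes that were not named. Il1b lost its call with replicates 1 to 3 only, where fewer samples were used, in STSABs (edgeR quasi-likelihood adjusted p = 0.0543, from 0.000238 over its alternatives) and in UVABs (0.135, from 0.000251), and in UVABs with library totals only (0.0824). Counts of called genes stayed within 1.5 times under all alternatives except library totals only, which gave 2365 higher and 8802 lower for LPS against Con, 2510 and 8511 for STSABs against Con, and 2504 and 8523 for UVABs against Con. They leave out TMM factors, which averaged 1.51 in Con and 0.902 to 0.932 in the other groups. The share moved toward Con in STSABs was 61.4% without a fold minimum, which takes in weaker genes, and 64.7% without the libraries numbered 2; in UVABs it was 61.4% and 64.8%, and 66.6% with all 5 LPS libraries on both sides, which by construction shares their chance values. With an estimated correlation 3 list calls held in place of 26, since the test then allows for co-varying members. Where the fit was changed as well, 2 held with the replicate block, 2 without the libraries numbered 2 and 0 with replicates 1 to 3 only, for which the cause was not tested. With a pseudocount of 0.1 the M2 score of UVABs against Con was lost (exact permutation, adjusted p = 0.321), and, as for the shares without the libraries numbered 2, the cause was not tested.

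Leaving out each library in turn gave 4823 to 5031 genes higher and 5194 to 5431 lower for LPS against Con, 3316 to 3669 and 3415 to 3724 for STSABs against LPS, and 3381 to 3652 and 3399 to 3701 for UVABs against LPS. It gave 4836 to 5038 and 5172 to 5384 for STSABs against Con, 4868 to 5043 and 5150 to 5353 for UVABs against Con, and 0 to 0 for UVABs against STSABs, with 186 to 324 at an unadjusted p under 0.05.

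With the replicate number as a block, 5012 genes were higher and 5356 lower for LPS against Con, 3657 and 3774 for STSABs against LPS, 3703 and 3755 for UVABs against LPS, 5016 and 5324 for STSABs against Con, 5040 and 5317 for UVABs against Con, and 0 and 0 for UVABs against STSABs (217 at an unadjusted p under 0.05). The block let Il12b pass against LPS (-0.41 in STSABs, -0.44 in UVABs) and Ccl5 in STSABs (0.20), and the mast cell and endothelial lists in UVABs against LPS (camera adjusted p = 0.0491 each, from 0.0323 to 0.665 over their alternatives; adjusted p = 0.573 and 0.397 with an estimated correlation), and it changed no other call of a named gene or list. Numbers paired only STSABs with UVABs. Without the pair numbered 2 the correlations were 0.149, 0.0890, 0.170 and 0.0508, so the pairing rests in part on that pair. Depth limits genes with few counts: of 617 intervals between UVABs and STSABs that reached 2-fold, 616 were of genes under a mean of 100 counts per AB library (median 6.1, against 333.6 for the other genes), and without the libraries numbered 2 the number was 707.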

Other observations

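The test of the ribosome biogenesis list was set before its members were looked at, but the list was drawn up only after Nop2, Rbm19, Nolc1 and Ddx21 had been seen to fall, and these were left out of it.

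Genes for making ribosomes were lower in both AB groups than in LPS. Of 30 list members, 29 fell and 1, Npm1, rose in each AB group (0.15 ± 0.06 and 0.19 ± 0.06), with medians of -0.83 in STSABs and -0.84 in UVABs (camera p = 1.58e-13 and 9.95e-14; p = 0.00119 and 0.00111 with an estimated correlation). Nop58, a core protein of the particles that methylate ribosomal RNA, was at 14.3 ± 0.736 CPM in LPS, 5.34 ± 0.798 in STSABs and 5.42 ± 0.754 in UVABs (SD, n = 5; -1.42 ± 0.10 and -1.39 ± 0.10). Noc2l changed by -0.81 ± 0.06 and -0.80 ± 0.06, Wdr75 by -1.45 ± 0.10 and -1.40 ± 0.10, and Heatr1, which acts in transcription and processing of ribosomal RNA, by -1.08 ± 0.08 and -1.04 ± 0.08. In LPS against Con 23 members fell and 4 rose (median -0.75), and the medians against Con were -1.64 in STSABs and -1.57 in UVABs. Between UVABs and STSABs 0 members were called by edgeR's quasi-likelihood test. Markers of other cell types moved in the same comparisons with LPS, as 16 of 16 neutrophil markers rose in STSABs and 14 in UVABs, and 6 of 8 mast cell and basophil markers in each.

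A hypothesis is that ribosome production may be lower in macrophages of the AB groups than in those of the LPS group. In its test at least 29 of 30 members fell. That outcome is weak support, since Nop2, Rbm19, Nolc1 and Ddx21, of the same process, had been seen to fall in these libraries beforehand. Counts of 29 and 1 were also found under DESeq2 size factors, upper-quartile scaling and library totals, and without the libraries numbered 2. Expression of these genes is not a measure of ribosome output, and the share of counts from ribosomal protein genes was higher in the AB groups than in LPS. Whether the AB groups received LPS, and for how long, is not stated, so a difference in time or dose could give the same picture and was not tested. A larger share of granulocytes would dilute macrophage markers as well. That list had medians of -0.05 in STSABs and 0.01 in UVABs, against -0.83 and -0.84 for ribosome biogenesis. These medians argue against dilution as the only source, although single macrophage markers moved both ways.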
